A study of Mus musculus with 8 samples.

How the data were processed

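Total RNA from buffy coats of 8 mouse samples, 4 exposed to PM2.5 and 4 given PBS over 24 weeks, was reverse transcribed with random primers and made into strand-marked libraries, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.17.1.14, cutadapt 1.9.1 and HISAT2 2.0.1 and the build GRCm38. The tool that counted, and whether it used strand, are not given in the sources used here, so reads of overlapping and antisense genes may not be told apart. The deposited table holds 118783 Ensembl transcripts with 1 column of expected counts and 1 of FPKM per library and a transcript length. The expected counts are estimated counts deposited by the authors without normalization, and 24.5% of the values are not whole. The deposited FPKM values were scaled by the authors by transcript length and by the fragments of each library, per the file headers.

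Here 116710 transcripts were matched by identifier to GENCODE M21 and summed to 35944 genes. The 2073 transcripts without a match held 0.0266% to 0.0532% of each library and were left out. No pair of libraries agreed within sampling noise, so no pair looked like repeat sequencing of a single library, and all 8 were kept. This check cannot tell whether each came from a separate animal. The design fixed before the data were examined named limma for a file of FPKM and edgeR where counts were given. Because expected counts were given, they were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, two-sided, filterByExpr with a minimum count of 10 and a minimum total of 15, TMM scaling over the kept genes). Levels are given as CPM of the TMM-scaled libraries, haemoglobin counts included. Benjamini-Hochberg adjustment covered all genes tested, with a threshold of 0.05, and every adjusted p of a gene is from this test. The SE of a log2 fold change is its size over the square root of the F statistic, an approximation. The labels name no batch, sex or pair, so the model held the group alone.

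Gene lists of cell types and pathways were fixed before the data were examined and tested with camera (limma 3.58.1, preset correlation 0.01) where at least 5 members were measured, adjusted over 32 lists. An estimated correlation, fry and exact permutation tests of list means (70 arrangements, smallest two-sided p 0.0286) were alternatives. Cell type measures on FPKM, the haemoglobin share and list means of log2(FPKM + 1), were compared by exact permutation tests adjusted over 15 measures.

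Genes named in the text were chosen by a rule fixed before the data were examined. First came the 12 highest and the 12 lowest log2 fold changes among genes past adjusted p 0.05 whose groups did not overlap, skipping predicted genes, RIKEN clones, pseudogenes and antigen receptor segments. Second came members of each list past adjusted p 0.05, up to 6 by smallest p, or otherwise up to 3 by smallest p. Cyp1a1, Cyp1b1, Ahrr, Tiparp, Nqo1, Hmox1, Mt1, Mt2, Il1b and Tnf were always included. Hp, Olfr639, Chil3, Cd74, Il1r2, Ighm, Igkc, Ftl1, Gpx1, Cat, Prdx2, the Y-linked genes and the brain-expressed genes were named after their values were seen. Some genes that the rule selects are not reported here.

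Alternatives planned before the data were examined were worded for FPKM and were translated to counts where the setting allowed. They covered the pseudocount (0.1 in place of 1), filters (none, or 5 FPKM in 4 libraries), scaling (library totals, median ratio, haemoglobin removed then totals, quantile), composition covariates, limma variants on log2(FPKM + 1) for genes at 1 FPKM or more in 4 libraries, thresholds, list tests and each library left out. Alternatives chosen after seeing the data were limma with a trend on log2(FPKM + 1), DESeq2 1.42.0, and leaving out PM2.5 replicates 17 and 18, or 9 and 21.

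The procedure was tested on simulated data for this comparison, with counts drawn for 10361 genes from the real means and library sizes. It recovered 22.4% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 100% of those changed 4-fold. There were 7 false calls, 4.8% of its calls. The changed genes lay outside the lists and above a minimum mean CPM that Jchain and Crispld2, named below, did not reach. Counts were drawn independently for each gene. Recovery of lower genes, and false calls where genes are correlated, were therefore not tested. Because haemoglobin took most counts, the depth for other genes was 9637639 to 12752766 counts per library.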

Results

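RNA was sequenced from the buffy coat, the white cell and platelet layer of centrifuged blood, of mice exposed for 24 weeks to PM2.5 (fine airborne particulate matter) or to PBS (phosphate-buffered saline, the control). Each group held 4 libraries, named here by the numbers in their labels: PM2.5 replicates 9, 17, 18 and 21, and PBS replicates 4, 10, 12 and 16. The labels do not say outright that each library came from a separate animal, so p-values measure the spread between these samples. Libraries held between 72081019 and 89032794 expected counts. The 4 haemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, markers of red cells and their precursors, took 87.7% ± 1.02 of the counts with PM2.5 and 85.6% ± 2.34 with PBS (SD, n = 4 each; exact permutation p = 0.143, two-sided). This left 10019500 ± 683403 counts per PM2.5 library and 11623681 ± 905788 per PBS library for every other gene (SD, n = 4 each; exact permutation p = 0.0857). Transcripts of the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were counted in all 8 libraries.

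The comparison asked which blood cell transcripts differed after exposure. Genes of neutrophils and monocytes were among the largest increases with PM2.5, and genes of B cells and several olfactory receptor genes were among the decreases. Ccr2, the chemokine receptor by which monocytes leave the bone marrow (chromosome 9, 124101950 to 124113557, GRCm38), was 6.52 ± 2.64 CPM (TMM-scaled) with PM2.5 and 1.63 ± 0.622 with PBS, a log2 fold change of 1.99 (SE 0.274, adjusted p = 0.0029). Mmp8, the neutrophil collagenase (chromosome 9, 7558456 to 7568485), was 1.52 ± 0.384 CPM against 0.368 ± 0.116, a log2 fold change of 2.04 (SE 0.268, adjusted p = 0.00288). Pgap1, which remodels the lipid anchor of surface proteins (chromosome 1, 54472994 to 54557684), was 3.54 ± 0.735 CPM against 10.1 ± 1.60, a log2 fold change of -1.51 (SE 0.185, adjusted p = 0.00221; SDs with n = 4 per group). Of 10361 genes tested with edgeR, 48 were higher and 118 were lower with PM2.5, 166 in all, and 1868 had an unadjusted p under 0.05. All PM2.5 libraries lay on one side of all PBS libraries in 155 of the 166, and in 9.7% of all genes tested, where chance gives 2.86%.

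**Figure D1:**
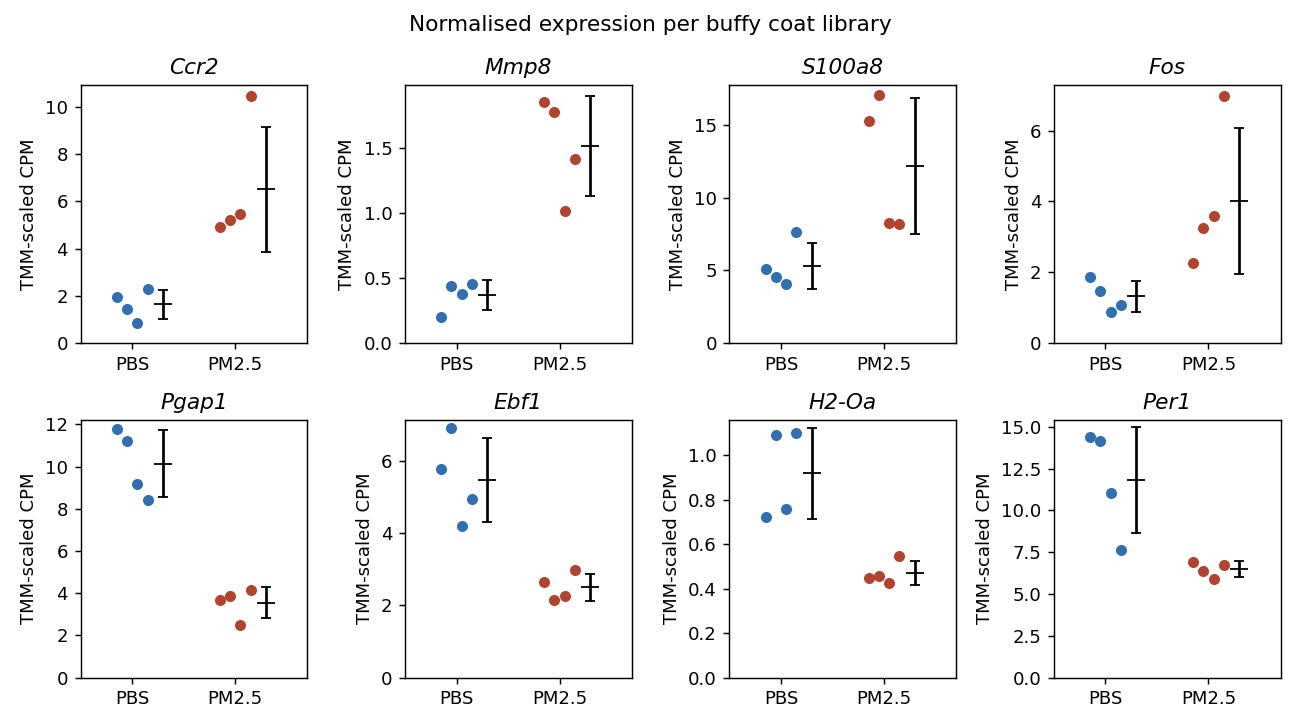
TMM-scaled CPM (vertical axes, from 0) of 8 genes in the 4 PBS (blue) and 4 PM2.5 (red) libraries, 1 point per library, with the mean and SD beside each group. Ccr2, Mmp8, S100a8 and Fos were higher and Pgap1, Ebf1, H2-Oa and Per1 lower in all 4 PM2.5 libraries than in any PBS library.

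The further increases selected by size included Jchain, the joining chain of secreted IgA and IgM, with a log2 fold change of 2.28 (SE 0.445), Vcan, a matrix proteoglycan made by monocytes, with 2.23 (SE 0.396; 1.47 without PM2.5 replicate 21, and adjusted p = 0.0625 without PBS replicate 10), and Crispld2 with 2.25 (SE 0.461). Cebpd, a transcription factor of myeloid cells, had a log2 fold change of 1.99, Slc27a2 1.97, Pxylp1 1.81, Siglece 1.74, Nlrp12 1.74, Kcnj2 1.71 and Fos 1.60. Each was higher in all 4 PM2.5 libraries than in any PBS library, which the rule that selected them required. Without PBS replicate 10 none of them passed (adjusted p = 0.0552 to 0.171). Pxylp1 lost its call whichever single library was left out. Among the decreases, Eif2ak3, the PERK kinase of the unfolded protein response, had a log2 fold change of -1.27 (SE 0.229), Pde3b, a cyclic nucleotide phosphodiesterase, -1.27 (SE 0.198), and Ero1lb, an oxidase of the endoplasmic reticulum, -1.15 (SE 0.181). Atxn7l2 was at -1.59, Clcf1 at -1.23, Sgip1 at -1.22, Vhl at -1.21 and Aim2 at -1.15, and none of these passed without PBS replicate 10 (adjusted p = 0.066 to 0.19). The olfactory receptor genes Olfr107 and Olfr365 were at -1.74 and -1.23, and such genes share sequence within their family, so their counts are uncertain. Olfr107 passed without PM2.5 replicate 21 (-2.485, adjusted p = 0.0119). It lost its call when any other single library was left out (adjusted p = 0.0519 to 0.131). Olfr365 did not pass without PBS replicate 10 (adjusted p = 0.0595). Many of these genes were low: Crispld2 was at 0.0698 CPM and Jchain at 0.0949 CPM with PBS.

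These counts moved with the libraries and the test. Without PM2.5 replicates 17 and 18, a choice made after seeing the data because those libraries held transcripts of brain-expressed genes, 8 genes passed (5 higher, 3 lower), of which Ccr2, Mmp8, Vcan, Hp, Pgap1 and Olfr639 also passed with all libraries. Leaving out PM2.5 replicates 9 and 21 instead, which removes as many libraries, gave 189. Without single libraries the count was 55 (PM2.5 replicate 17), 69 (PM2.5 replicate 18), 85 (PM2.5 replicate 21), 87 (PBS replicate 4) and 31 (PBS replicate 10). On log2(FPKM + 1), limma called 0 genes with a trend (716 at an unadjusted p under 0.05), and 474 (5 higher, 469 lower) with array weights, a fit that stopped before converging. With the trend form Ccr2 was at 0.71 (adjusted p = 0.171). With all libraries, edgeR called 0 genes with the erythroid list mean as a covariate (955 unadjusted) and 3 with the mature neutrophil minus B cell list mean. Scaling to library totals gave 8 higher and 475 lower genes, with the median log2 change of all genes at -0.52 in place of 0.05, and Ccr2 was at 1.40 (adjusted p = 0.0175), S100a8 at 0.60 (0.22), Mmp9 at 0.56 (0.288), Ncr1 at 0.72 (0.277) and Tlr2 at 0.42 (0.444). Removing haemoglobin and then scaling to totals gave 10 and 216, with that median at -0.30.

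Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01, and 13 of 32 passed, 10 higher and 3 lower. None of the 13 passed with an estimated correlation, or by fry. An exact permutation test of list means gave the smallest p it allows, 0.0286, in 7 of the 32 lists. These were the monocyte, NK, interferon, aryl hydrocarbon receptor, oxidative stress, pattern recognition and MHC class II lists. Adjusted over 32 lists the exact test passes 0.05 only where most lists reach that p, so its lack of calls carries little weight. Fry's mixed test, which asks for change in either direction, passed 19. Under scaling to library totals the medians of the monocyte, NK, erythroid, platelet, interferon, oxidative stress, pattern recognition, immediate early and glycolysis lists were below 0, and relative to all genes they stayed above it. Under that scaling 9 of the 13 passed, and the oxidative stress (adjusted p = 0.0623), glycolysis (0.0624), platelet (0.0872) and immediate early lists (0.106) did not. Quantile normalization kept 8. Under it the median was 0.002 for erythroid genes (adjusted p = 0.687), 0.05 for platelet (0.716), 0.09 for oxidative stress (0.122), 0.117 for immediate early (0.153) and 0.12 for glycolysis genes (0.0879). With haemoglobin removed, the immediate early list did not pass (median -0.05, adjusted p = 0.0752). With the erythroid covariate the NK (adjusted p = 0.0983) and oxidative stress lists (0.0504) did not pass. With the neutrophil minus B cell covariate the NK (0.35), erythroid (0.117), oxidative stress (0.136), pattern recognition (0.136), glycolysis (0.0743) and glucocorticoid lists (0.151) did not. With limma's trend form on log2(FPKM + 1) the monocyte (0.0849), platelet (0.103), oxidative stress (0.103), immediate early (0.461) and glycolysis lists (0.715) did not.

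Neutrophil genes were higher as a list (median log2 change 0.92, camera adjusted p = 7.17e-05; adjusted p = 0.508 with an estimated correlation). Of 10 measured members, S100a8, a calcium-binding protein of neutrophil cytosol, rose by 1.19 (SE 0.253), Mmp9, gelatinase B, by 1.19 (SE 0.281) and Cxcr2, a chemokine receptor, by 0.94 (SE 0.231), and 7 did not pass. Adjusted over the list alone, 6 were higher and 1, the decoy receptor Il1r2, was lower. S100a8, Mmp9 and Cxcr2 each lost their call without PM2.5 replicate 9 or 17, or PBS replicate 4, 10 or 12 (adjusted p = 0.0565 to 0.229). Cxcr2 also lost it without PM2.5 replicate 18 (0.085). The groups overlapped for Mmp9 and Cxcr2. The granule list had 3 measured members, too few for camera, of which Mmp8 and Lcn2 (1.47, SE 0.328) rose. Lcn2 did not pass without PM2.5 replicate 9 or 17, or PBS replicate 4, 10 or 12 (adjusted p = 0.0517 to 0.15). Monocyte genes were higher (median 0.43, adjusted p = 7.17e-05; adjusted p = 0.478 with an estimated correlation). In this list Vcan, Ccr2 and Ms4a6c (1.04, SE 0.201) rose, 11 of 14 did not pass, and 3 were higher adjusted over the list alone. The haemoglobin share given above (87.7% with PM2.5 and 85.6% with PBS) did not pass its exact permutation test (p = 0.143). The erythroid list moved with these groups, with 18 of 18 members positive and none past the test (median 0.52, adjusted p = 4.49e-05; adjusted p = 0.508 with an estimated correlation). Platelet genes had a median of 0.31 with 13 of 13 positive and none past the test (adjusted p = 0.0116; adjusted p = 0.631 with an estimated correlation). Genes of natural killer cells had a median of 0.36 (adjusted p = 0.0275; adjusted p = 0.508 with an estimated correlation), and Ncr1, an activating receptor, rose by 1.40 (SE 0.344). Ncr1 lost its call when any single library except PM2.5 replicate 9 was left out (adjusted p = 0.0537 to 0.159). Its log2 change was 1.03 without PM2.5 replicate 17. Without PM2.5 replicates 17 and 18 the median was 0.18 for natural killer genes (camera adjusted p = 0.303) and 0.13 for erythroid genes (adjusted p = 0.075). Without PM2.5 replicates 9 and 21 it was 0.16 for monocyte genes (adjusted p = 0.036) and 0.15 for platelet genes (adjusted p = 0.529). The natural killer call was also lost without PM2.5 replicate 17 (adjusted p = 0.151), PBS replicate 4 (0.0851) or PBS replicate 12 (0.119), and the platelet call without PM2.5 replicate 9 (median 0.19, adjusted p = 0.107) or PBS replicate 16 (median 0.19, adjusted p = 0.113).

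**Figure D2:**
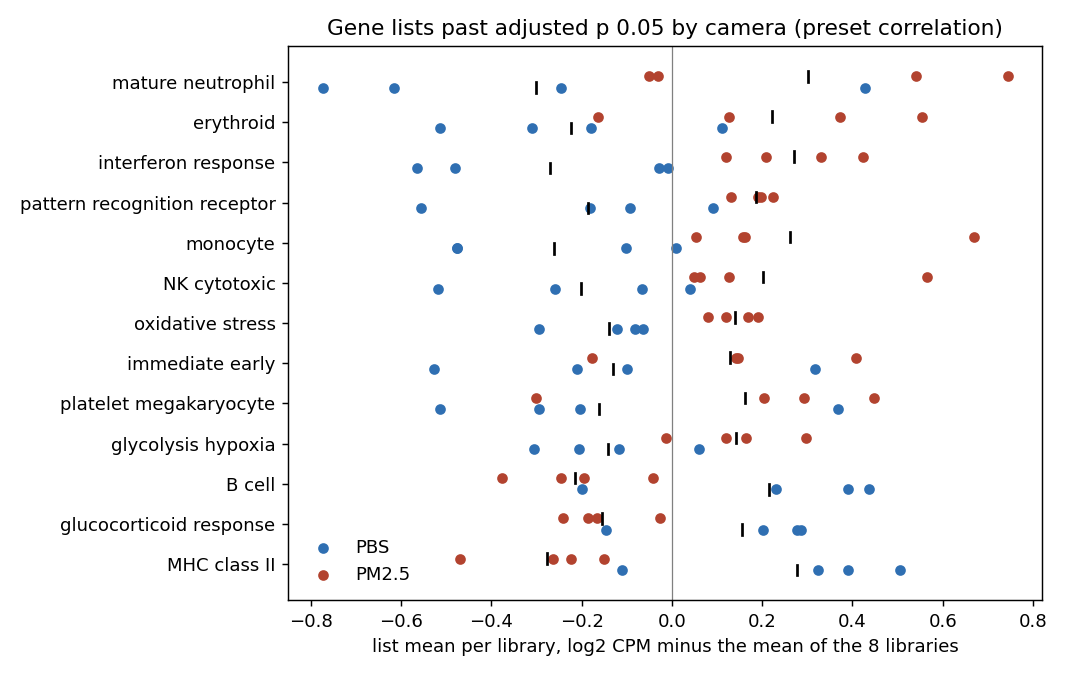
Mean log2 CPM of each of the 13 gene lists past camera's preset-correlation test, per library, less the mean of the 8 libraries (horizontal axis), with PBS in blue, PM2.5 in red and black bars at the group means. The groups lie apart in the monocyte, natural killer, interferon, oxidative stress, pattern recognition and MHC class II lists. They overlap in the mature neutrophil, B cell, erythroid, platelet, immediate early, glycolysis and glucocorticoid lists.

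B cell genes were lower (median -0.32, camera adjusted p = 2.4e-06; adjusted p = 0.478 with an estimated correlation). Ebf1, the B lineage transcription factor, was at -1.12 (SE 0.177), the kinase Blk at -0.81 (SE 0.193) and the adaptor Bank1 at -0.79 (SE 0.194), 11 of 14 did not pass, and 4 were lower adjusted over the list alone. The groups overlapped for Blk and Bank1. Both lost their calls when any single library except PBS replicate 12 was left out (adjusted p = 0.0556 to 0.166). The MHC class II genes, which present antigen, were lower (median -0.57, adjusted p = 8.03e-07; adjusted p = 0.478 with an estimated correlation). H2-Oa, a modulator of peptide loading made by B cells, was at -0.96 (SE 0.234), 9 of 10 did not pass over all genes, and 9 passed adjusted over the list alone. H2-Oa lost its call when any single PM2.5 library, or PBS replicate 10 or 16, was left out (adjusted p = 0.0718 to 0.168). With the erythroid covariate the median was -0.17 for B cell genes (adjusted p = 0.00665) and -0.36 for MHC class II genes (adjusted p = 0.000704). Cd74 was 52.5 ± 5.63 CPM with PM2.5 and 75.3 ± 11.5 with PBS (SD, n = 4 each). Glucocorticoid-responsive genes were lower (median -0.37, adjusted p = 0.0066; adjusted p = 0.478 with an estimated correlation), with the clock gene Per1 at -0.86 (SE 0.194) as the member that passed of 11, and 3 lower adjusted over the list alone; without PM2.5 replicates 9 and 21 the list had a median of -0.40 (adjusted p = 0.101). T cell genes did not pass (adjusted p = 0.558), with a median of 0.12 against a mean of -0.06 and a camera direction downward. In the plasma cell list (median 0.07, adjusted p = 0.403), Jchain and Igha, the IgA constant region (2.39, SE 0.483), rose. Of its 8 measured members 4 were positive, and the more abundant Ighm (-0.38, SE 0.192) and Igkc (-0.42, SE 0.181) were lower without passing. The groups overlapped for Igha, which lost its call without PM2.5 replicate 18 or 21 or PBS replicate 4 or 10 (adjusted p = 0.0548 to 0.0698).

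Interferon-response genes were higher as a list (median 0.51, 17 of 19 positive, camera adjusted p = 2.26e-05; adjusted p = 0.478 with an estimated correlation). No member passed over all genes, while 7 passed adjusted over the list alone, among them Usp18 (0.93, SE 0.253) and Oasl2 (1.00, SE 0.277). The median was 0.295 with the erythroid covariate (adjusted p = 0.047), 0.255 with the neutrophil minus B cell covariate (adjusted p = 0.0101) and 0.22 at 5 FPKM or more (adjusted p = 0.178). Pattern recognition receptors were higher (median 0.46, adjusted p = 0.00344; adjusted p = 0.478 with an estimated correlation), and Tlr2, the receptor for bacterial lipopeptides, rose by 1.02 (SE 0.194). Oxidative stress genes had a median of 0.33 with 19 of 22 positive and none past the test (adjusted p = 0.0017; adjusted p = 0.478 with an estimated correlation). Its most abundant members, Ftl1 (1738 ± 347 CPM with PM2.5), Gpx1 (1667 ± 586), Cat (768 ± 193) and Prdx2 (680 ± 171; SD, n = 4), are also abundant in red cells. The erythroid list moved with them, and with the erythroid covariate the oxidative stress median was 0.09 (adjusted p = 0.0504). Immediate early genes had a median of 0.33 (adjusted p = 0.0408; adjusted p = 0.631 with an estimated correlation), with Fos the member that passed of 17, and glycolysis genes had 0.26 with none past the test (adjusted p = 0.0207; adjusted p = 0.508 with an estimated correlation). Immediate early genes had a median of 0.20 (adjusted p = 0.0739) without PM2.5 replicates 17 and 18 and 0.22 (adjusted p = 0.239) without replicates 9 and 21. Their call was also lost without single libraries, with a median of 0.12 without PM2.5 replicate 17 (adjusted p = 0.101), 0.25 without PM2.5 replicate 18 (0.0625), 0.10 without PM2.5 replicate 21 (0.23), 0.135 without PBS replicate 12 (0.57) and 0.145 without PBS replicate 16 (0.0817). Without PBS replicate 12 the adjusted p was 0.0597 for pattern recognition receptors and 0.0858 for glycolysis genes, and without PM2.5 replicate 9 it was 0.122 for glycolysis genes (median 0.16). Without replicates 9 and 21, pattern recognition receptors had a median of 0.34 (adjusted p = 0.0677) and glycolysis genes 0.19 (adjusted p = 0.392).

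The aryl hydrocarbon receptor list, which holds targets of a sensor of polycyclic hydrocarbons, did not pass (median 0.26, camera adjusted p = 0.396). Cyp1a1 had 0 counts in all 8 libraries, Cyp1b1 had 8 in PM2.5 replicate 9 and 4 in PBS replicate 4 and 0 elsewhere. Ahrr had 1 count in PBS replicate 16 and 0 elsewhere. These were not detectable at this depth or too low to test. Tiparp had a log2 fold change of 0.06 (SE 0.194), Nqo1 -0.04 (SE 0.163), Hmox1 0.38 (SE 0.318) and Il1b -0.11 (SE 0.384), none past the test. Mt1, a metal-binding protein, was at 1.52 (SE 0.548, adjusted p = 0.169), and Mt2 and Tnf were under the filter. The metal response list did not pass (adjusted p = 0.0893), nor did inflammatory cytokines and NF-kB genes (adjusted p = 0.8), of which Socs3, a feedback inhibitor of cytokine signalling, rose by 1.31 (SE 0.237).

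The remaining lists did not pass camera at adjusted p 0.05. Circadian clock genes had a median of -0.35 (adjusted p = 0.0903), with Nfil3 at 1.02 (SE 0.175) and Per1 passing in opposite directions. Mitochondrially encoded genes had a median of 0.25 (adjusted p = 0.0893), nuclear oxidative phosphorylation genes 0.15 (adjusted p = 0.0903), and proliferation genes 0.27 (adjusted p = 0.12). Apoptosis regulators had 0.19 (adjusted p = 0.744), with Bcl2l11, which encodes the death-promoting protein BIM, at -0.75 (SE 0.174). Cholesterol and lipid genes had a median of 0.08 and a mean of -0.01 with a camera direction downward (adjusted p = 0.749), with the cholesterol exporter Abca1 at -0.73 (SE 0.165). The p53 list had a median of 0.05 and a camera direction downward (adjusted p = 0.92), with the DNA repair gene Ddb2 at -1.13 (SE 0.257). Heat shock genes had a median of 0.01 and a mean of -0.11 (adjusted p = 0.429). Medians were 0.15 for the unfolded protein response (adjusted p = 0.92), -0.18 for dendritic cells (adjusted p = 0.361), -0.22 for eosinophils and basophils (adjusted p = 0.749), 0.23 for progenitors (adjusted p = 0.744) and 0.24 for endothelium (adjusted p = 0.543). Ribosomal protein genes had a median of 0.08 (adjusted p = 0.749), and under several other settings, given below, they passed as lower. The muscle, skin and liver list had 1 measured gene, Mylpf (-0.07, SE 0.444), and was not tested.

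On the FPKM scale, without scaling beyond the authors' own, no cell type measure passed an exact permutation test adjusted over 15 measures, which can pass only where most measures reach the smallest p. The haemoglobin genes took 96.8% ± 0.365 of FPKM with PM2.5 and 96.3% ± 0.557 with PBS (SD, n = 4 each; exact p = 0.143, adjusted p = 0.557). The B cell list mean was 1.29 ± 0.276 against 1.97 ± 0.457 on the log2(FPKM + 1) scale (n = 4 each; exact p = 0.0857, adjusted p = 0.557). The T cell list mean was 0.958 ± 0.189 against 1.27 ± 0.208 (n = 4 each; exact p = 0.0571, adjusted p = 0.557). The monocyte list mean was 1.84 ± 0.371 against 1.95 ± 0.308 (n = 4 each; exact p = 0.714, adjusted p = 0.765), a difference opposite in sign to that of the TMM-scaled counts. The same held for the list means of natural killer (0.707 ± 0.0977 against 0.803 ± 0.164), erythroid (9.24 ± 0.106 against 9.33 ± 0.1398) and platelet genes (5.05 ± 0.633 against 5.27 ± 0.585), and for the plasma cell, progenitor and endothelial lists, each with an exact p of 0.343 or more. The mature neutrophil list mean was 1.53 ± 0.3004 against 1.46 ± 0.355 (n = 4 each; exact p = 0.714, adjusted p = 0.765).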

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

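In groups of 4 libraries, 1 library was far from the others, by a gap to its nearest neighbour, as a share of the group's range, above Dixon's 95% critical value, in 20 of 268 groups looked at (7.5%). Chance gives about 1 in 20, and no explanation was tested. Values below are that share of the range.

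Among PBS libraries, replicate 16 was high for Nlrp12 (0.961), Cxcr2 (0.87), Pgam1 (0.887) and Hmox1 (0.862) and low for Bcl2l11 (0.974). Replicate 10 was high for Clcf1 (0.892), Ddb2 (0.892) and the mean of the apoptosis list (0.841). Replicate 12 was high for Slc39a14 (0.874) and Tpx2 (0.941) and low for Nfil3 (0.897). Replicate 4 was high for the mean of the endothelial list (0.837).

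Among PM2.5 libraries, replicate 9 was high for Pde3b (0.923) and the means of the eosinophil and basophil list (0.838) and the progenitor list (0.84), and low for the mean of the plasma cell list (0.873) and for depth (0.976), at 72758187 counts against 84724888 in the nearest library. Replicate 21 was high for Ccr2 (0.854), at 3.39 log2 CPM against 2.46, and for counts outside haemoglobin (0.95), at 11043664 counts against 9705797. Replicate 17 was high for the mean of the natural killer list (0.851).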

How the results depend on the processing

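The settings limma with a trend, DESeq2, and PM2.5 replicates 17 and 18 or 9 and 21 left out were chosen after seeing the data. With all libraries, 166 genes passed (48 higher, 118 lower). The count was 0 with limma on log2 FPKM with a trend, without one, robust or with a pseudocount of 0.1, where 3658 genes were tested, and 0 with edgeR at 5 FPKM or more, where 1108 were tested and 85 had an unadjusted p under 0.05. It was 0 with the erythroid covariate and 3 (2 higher, 1 lower) with the neutrophil minus B cell covariate, 474 (5, 469) with limma's array weights, whose fit stopped before converging, 371 (109, 262) with DESeq2, 624 (313, 311) with no filter and 483 (8, 475) with library totals. Haemoglobin removed then totals gave 226 (10, 216), the median ratio 174 (49, 125), quantile normalization 129 (29, 100), replicates 17 and 18 left out 8 (5, 3), and replicates 9 and 21 left out 189 (108, 81). At an unadjusted p under 0.05 it was 1868 (911, 957), at adjusted p under 0.10 it was 356 (115, 241), and with a 2-fold change as well 72 (33, 39). Without single libraries it ranged from 31 to 192 (higher 6 to 66, lower 25 to 134). Leaving out replicates 9 and 21 removes as many libraries as leaving out 17 and 18, so fewer libraries alone do not account for the 8. Of the 166 genes, 6 passed without replicates 17 and 18 and 80 without 9 and 21. Why the calls leaned on replicates 17 and 18 was not tested. For the other settings the cause was not tested, apart from the fewer genes named.

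With all libraries 13 lists passed. The number was 7 with each form of limma on log2 FPKM, 6 of them among the 13, of which 11 could be tested, and 3 at 5 FPKM or more, 2 of them among the 6 of the 13 tested. It was 8 with replicates 9 and 21 left out, all among the 13, and 0 with an estimated correlation, fry and the exact permutation test. Without single libraries it ranged from 11 to 14, with 9 (PBS replicate 12) to 13 of the 13 kept. Directions turned for mature neutrophil genes with the neutrophil minus B cell covariate, which holds that list (adjusted p = 0.0321), for erythroid genes with the erythroid covariate, which is that list (adjusted p = 0.852), and for glycolysis genes at 5 FPKM or more (adjusted p = 0.551). Ribosomal protein genes turned to lower with limma's trend, no trend and robust forms, which share the same list test (camera adjusted p = 1.25e-06). They also did so with array weights (2.3e-05), pseudocount 0.1 (0.000811), quantile normalization (0.00365), 5 FPKM or more (9.34e-09) and the erythroid covariate (9.96e-06). The cause was not tested. No cell type measure passed under any of its alternatives.

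Of 43 named genes that passed, none turned where it was tested, which was 14 of them with limma on log2 FPKM and 1 at 5 FPKM or more. DESeq2 and no filter kept 43, the median ratio 42, quantile normalization 32, haemoglobin removed 27, library totals 25, replicates 9 and 21 left out 22, replicates 17 and 18 left out 4, the neutrophil minus B cell covariate 2 and the erythroid covariate 0. Limma kept 9 of 14 with array weights and 0 of 14 in its other forms, and 5 FPKM or more kept 0 of 1. Single libraries left out kept 7 (PBS replicate 10) to 33 (PBS replicate 16). No paired analysis was possible because the groups share no replicate numbers.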

Other observations

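Transcripts of olfactory and vomeronasal receptors, which are genes of sensory neurons, were seen among the decreases. The families were looked at after the genes that passed had been seen, so the counts describe these calls and are no independent test. Of 77 such genes tested with edgeR, 17 passed as lower (22.1%), against 101 of 10284 other genes (0.98%). The olfactory family had 12 of 47 lower and 0 higher (median log2 change -0.71), and the vomeronasal family 5 of 30 lower and 1 higher (median -0.84). In 1228 of 1407 olfactory receptor genes no count was seen in any library.

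Among the tests below, those of repeats and of summed neuron and glia genes were fixed before their results were seen; the others were chosen after. For the receptor families, scaling is argued against: a factor per library cannot set them apart from other genes, from which the median of the 77 differed by -0.734 to -0.815 over the 5 scalings, and quantile normalization, which is no such factor, left it at -0.72. Reads from genomic DNA that covered the family evenly would spread over it, and 98% of the olfactory receptor counts lay in 71 of its genes. Genomic reads from repeats within those genes could gather there alike, so the spread does not argue against them. Repeats shared with other transcripts stay open: the receptor genes that passed had a median of 10.6% of their 25-mers in 10 or more genes, against 0.325% for those under the filter. Other genes in the top 10% by that share had a median change that differed from that of genes with none by -0.086 (bootstrap 95% interval -0.12 to -0.06), between the bounds set beforehand. A candidate explanation is that these counts come from repeats in other transcripts; an effect of exposure was not tested apart from it.

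For the monocyte genes, their list means argue against PM2.5 replicates 17 and 18 as the whole source. Less the mean of the 8 libraries, these were 0.157 and 0.053, under 0.163 in replicate 9 and 0.67 in replicate 21. Leaving out replicates 17 and 18 could therefore hardly lower the difference. The median was then 0.42, and Vcan and Ccr2 passed edgeR's test. Both leaned on replicate 21, with Ccr2 at 10.5 CPM against 4.90 in replicate 9 and Vcan at 4.31 against 1.01. For the mature neutrophil genes, replicates 17 and 18 as the whole source stay open. Without replicates 17 and 18 their median was 0.72, but no list member passed, and only Mmp8 and Chil3 of the granule list did. The mature neutrophil list mean, less the mean of the 8 libraries, was 0.541 in PM2.5 replicate 9. It was -0.05 in PM2.5 replicate 21, below PBS replicate 16 (0.428). At the preset correlation camera's adjusted p without replicates 17 and 18 was 8.55e-05 for neutrophil and 1.2e-08 for monocyte genes. Without replicates 9 and 21 it was 0.00112 and 0.036 (medians 0.92 and 0.16). With all libraries neither list passed with an estimated correlation (adjusted p = 0.508 and 0.478). A factor per library cannot set the lists apart from other genes, and relative to all genes the medians lay between 0.831 and 0.872 and between 0.325 and 0.396 over the 5 scalings, with camera adjusted p of 0.00342 and 0.00826 under quantile normalization, where the exact p of the list means were 0.114 and 0.0857. Whether these genes rose or the others fell stays open with the scaling, since library totals moved the median of all genes to -0.52, with the neutrophil median at 0.31 and the monocyte median at -0.14 (exact permutation p of 0.943 and 0.914 for the list means). A lower share of B cells may raise other cell types alike; the neutrophil median lay 0.80 above the T cell median, but the difference of list means had an exact p of 0.171, so this stays open, as do a changed cell composition and a change within cells, which these data do not separate.

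PM2.5 replicates 17 and 18 held 19 genes at 15 or more counts in both and over 4 times every other library, among them Camk2a (78 and 97 counts), Snap25 (29 and 29) and Snhg11 (44 and 42), where no other pair of the 28 pairs of libraries gave more than 7. The test fixed beforehand failed: 28 held-out neuron genes summed to 0.883 times the highest other library, and 12 glia genes to 0.412 times, under the bound of 2 set against brain RNA, and by such sums 0 PM2.5 libraries lay above every PBS library. That bound was a poor one, since genes counted in every library, such as Vamp2 with 105 to 337 counts, made up 91.3% and 97.9% of the sums in the other libraries. Counted gene by gene, a test chosen after that failure, 13 of the 28 neuron genes had their highest counts in both replicates (at most 2 in any other pair), among them Cplx2 (24 and 38 counts) and Mapt (17 and 12), and 4 of the 12 glia genes (at most 1), while the most abundant neuron gene, Vamp2 (105 and 148), was not raised. By the same count 0 neuron genes were above every PBS library in all 4 PM2.5 libraries. The 19 genes were picked for counts over 4 times every other library, the other PM2.5 libraries included. Neuron genes of that kind could hardly be high in all 4, so this count cannot decide whether exposure was a shared cause. A candidate source is a trace of neuronal RNA or reads, and where it entered was not tested.

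All 35 splits of the 8 libraries into groups of 4 were compared, a check made after the counts were seen. The real split was the 1 that called as many as 166 genes, and the highest other split called 5. This argues against chance for that count, at 1 of 35 splits, the smallest share the check can give. It cannot tell exposure from another difference between the groups. For the lists chance is not argued against: 2 of the 35 splits called as many as 13, and the highest other split called 13.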
